A study of Mus musculus with 24 samples.

How the data were processed

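The 24 arrays measured total RNA of cultured mouse embryos, heat-shocked against control, in 2 channels per array. The values are the authors' log ratios, deposited as a processed value table for each of 2 slide types, and are treated here as a score with no stated unit. The base of the log, the numerator, the background correction and the normalization are not given in the sources used here. The tables held 7680 probes and 12 arrays each, with 0 missing values and 0 columns left unmapped. Log base 2 and natural log could not be told apart, so 1 unit and the limit of 0.58 units are given as folds for both. No spot intensities were used, so dim or saturated spots could not be set apart.

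The channel of the heat-shocked RNA was taken from the labels' source names. The value was taken as channel 1 over channel 2, and arrays with heat-shocked RNA in channel 2 had their sign turned. This sets the positive side by convention only. Scale and direction therefore stay unknown, and the deposited values were not centred on a common median. With heat-shocked RNA in channel 1, deposited array medians on slide type 1 were 0.29 and 0.53 for treatment 1, 0.15 and 0.32 for treatment 2, and 0.64 and 0.65 for treatment 3. With it in channel 2 they were −0.16 and −0.04, 0.02 and 0.17, and −0.67 and −0.38. On slide type 2 the medians with heat-shocked RNA in channel 1 were −0.24 and 0.24 for treatment 1, −1.51 and −1.30 for treatment 2, and −0.40 and −0.18 for treatment 3. With it in channel 2 they were −0.30 and 0.08, −1.28 and −1.18, and −1.01 and −0.69. Each array was centred on its median over all probes.

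The plan made before the data were examined took a suffix B in the slide codes for the slide type and expected 6 treatments per slide type. The tables showed otherwise. The number after the dot in the treatment name goes with the table, hence with the slide type, and arrays with and without the suffix share a slide code and a table. What the suffix marks is not stated. The planned fit of 6 values with the treatment as a random block is therefore given as an alternative. In its place, the 4 arrays of a treatment and slide type (2 channel orders, with and without the suffix) were averaged, with both channel orders weighted equally, and the 3 treatments were the replicates. The planned comparison of the numbers after the dot could not be made, because they are on different probes.

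Changes were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on an intercept for each slide type, and Benjamini-Hochberg adjustment at 0.05 over all probes or genes of a slide type. Gene values are means of all probes that carry that 1 symbol, from the platform annotation paired with the probes. Where probes of a named gene lay over 0.2 units apart, their range is given. Probes with several symbols or none entered only the counts of probes. The treat function of limma tested against 0.58 units.

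Of 25 gene lists fixed beforehand, 18 were of pathways and 7 of cell type markers, the latter being erythroid, yolk sac endoderm, heart muscle, neural, endothelial, mesenchyme and neural crest, and trophoblast. Lists with at least 5 measured members on a slide type were tested with camera at a preset inter-gene correlation of 0.01, which gave 38 tests (20 on slide type 1 and 18 on slide type 2) adjusted together. Camera with an estimated correlation and fry were alternatives. The rule for named genes, fixed in advance, took the 10 genes with the largest mean on each side per slide type that passed the test with the same sign in every treatment, up to 4 members of each list with the smallest p, and 13 genes fixed by name. It named 146 gene values, of which 91 are given. A further 32 values, 22 of them in the closing section, were chosen after they were seen.

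The tests were checked on simulated data with the probes' own spreads for 3 treatments and 200 changed probes of 7680 per slide type. On slide type 1, 78 of 100 changes of 0.5 units and 95 of 100 changes of 1 unit were recovered, and 7 of 7480 unchanged probes were called. On slide type 2 these numbers were 80, 95 and 5. The simulated noise was independent between probes and treatments, whereas genes on the real arrays were correlated. Camera estimated a correlation of 0.73 and 0.92 among ribosomal protein genes on slide types 1 and 2. On slide type 2 far more probes than the simulated 200 were called (4096), so the check does not give the rate of false calls in the real data. Other settings tried were no centring, a common spread, other ways to join the arrays, 1 channel order, a robust prior, leaving out each treatment, a correction for position on the slide and centring on named probes. Without centring, the offset of each treatment stays in every gene and widens the spread between treatments. A call lost in that setting may come from that spread, from the moved 0 or from both. Figures were drawn with matplotlib 3.10.9.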

Results

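Mouse embryos in culture were heated to 43 °C for 15 min, returned to 37 °C and taken 1 h later. Their total RNA was set against that of embryos kept at 37 °C on arrays with 2 channels. The 24 arrays came from 3 numbered treatments. Each treatment was hybridised to 2 slide types carrying different probes, with heat-shocked RNA in channel 1 on some arrays and in channel 2 on others, so that a treatment had 4 deposited arrays per slide type. In each channel order 1 of the 2 arrays has a suffix in its slide code, and whether it is a second hybridisation, another part of the slide or a second scan is not stated. The 4 arrays were averaged to 1 log ratio per probe, and the 3 treatments were taken as the replicates. Nothing in the labels says that the 3 treatments used separate litters, so the p-values speak of these treatments only, and their number limits the precision. The p-values do not rest on the SD of a gene alone, since limma moderates it with a spread pooled over the slide type. The gene Egr1, on 1 probe of slide type 2, had unadjusted limma p = 1.6e-06 in the fit of probes and 4.79e-09 in that of genes. Each slide type held 7680 probes. On slide type 1, 4749 probes carried 1 gene symbol, 227 several and 2704 none, and on slide type 2 these numbers were 4935, 275 and 2470.

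Neither the base of the log nor the numerator of the ratio is stated, so values are given in log units and by side. A difference of 1 unit is 2-fold if the base is 2, and 2.72-fold if the log is natural. The positive side is heat shock over control if the deposited ratio is channel 1 over channel 2, and control over heat shock otherwise. A mirrored sign would exchange the sides and leave every size and count as given. The direction stays unsettled, because the numerator is not stated. Some arrays of the same channel order correlated below 0 on slide type 2, with a lowest r of −0.34 over all probes, between arrays of treatments 1 and 2. There the channel component, which the average over channel orders removes, had r = −0.33 between these treatments and an SD of 0.608 in treatment 2. On slide type 1 the lowest r between arrays of the same order was 0.29. After the 2 channel orders were averaged, all treatments ran the same way: they correlated at r = 0.70 to 0.80 across the probes of slide type 1 and at 0.82 to 0.90 on slide type 2, over probes that are not independent replicates.

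The comparison asks which transcripts differed between heat-shocked and control embryos 1 h after the heat. Large positive values were found for heat shock proteins and immediate early transcription factors. Hsph1, an Hsp110 family chaperone, had a log ratio of 2.28 ± 0.50 (SD, n = 3 treatments, limma adjusted p = 1.1e-05), and Hspb1, the small heat shock protein Hsp27, one of 2.23 ± 0.05 (limma adjusted p = 5.27e-14). Jun and Egr1, transcription factors induced early by many stimuli, had 1.97 ± 0.33 and 1.74 ± 0.72. Txnip, the thioredoxin-interacting protein, and the receptor kinase Mst1r lay in the same range, at 1.85 ± 0.22 and 1.78 ± 0.06. The opposite side held Srsf5, a splicing factor, at −1.27 ± 0.33, the surface protein Cd24a at −1.22 ± 0.16, the growth arrest protein Gas1 at −1.21 ± 0.12 and the endoplasmic reticulum chaperone Hspa5 at −0.81 ± 0.22.

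**Figure D1:**
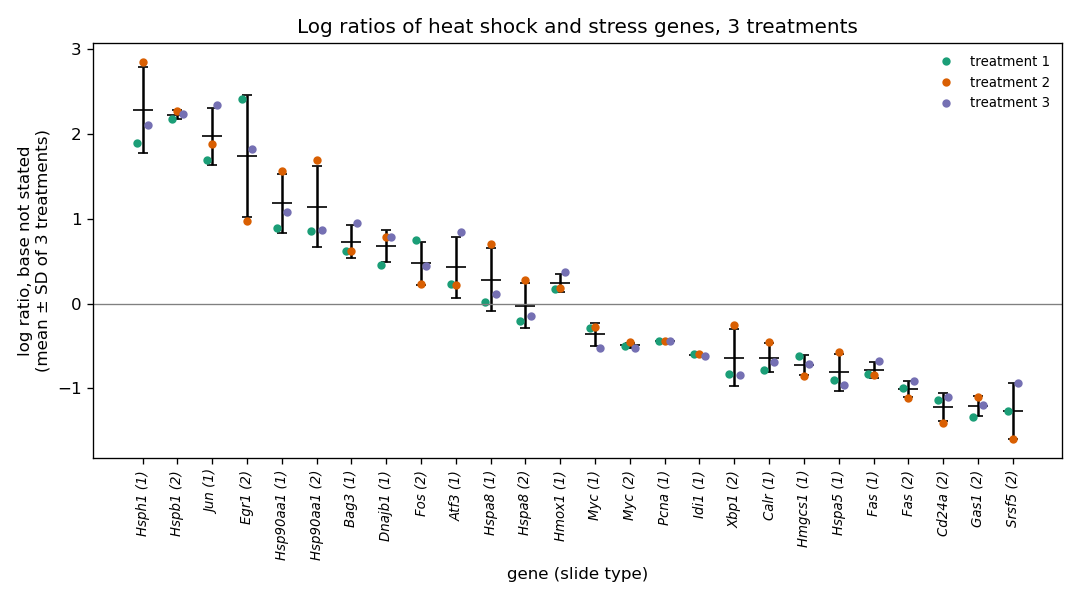
Log ratios (vertical axis, base not stated) of stress genes and of genes on the negative side, with the slide type in parentheses. Coloured points are the 3 treatments, and black bars are the mean ± SD. Hsph1 and Hspb1 lie above 1.8 in all 3 treatments, while treatment 2 stands apart for Egr1 (0.98) and Xbp1 (−0.25).

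Of 21 measured members of the heat shock chaperone list on slide type 1, 7 were changed on the positive side and 0 on the negative side. The same counts were found adjusted over the list alone. The 7 include Hmox1, heme oxygenase 1, an enzyme and not a chaperone. Hsp90aa1, the stress-inducible cytosolic Hsp90, had 1.18 ± 0.35 over 7 probes that ranged from 0.90 to 1.31, and 1.14 ± 0.48 on slide type 2. Bag3, a co-chaperone of Hsp70, had 0.73 ± 0.19, and Dnajb1, an Hsp40 protein, 0.68 ± 0.19 over 2 probes at 0.46 and 0.89. Hspa8, the constitutive Hsp70, did not pass the test on either slide type, with 0.28 ± 0.37 (limma adjusted p = 0.15) on slide type 1 and −0.03 ± 0.26 (limma adjusted p = 0.788) on slide type 2. It passed on slide type 1 when arrays were not centred, at 0.58, and had 0.07 there without treatment 2, and it passed on the negative side of slide type 2 without treatment 2, at −0.18. On slide type 2, 5 of 15 chaperones were changed on the positive side, led by Hspb1, and 6 on the negative side, with the same counts adjusted over the list alone. Over all genes, 220 of 3838 were positive and 217 negative on slide type 1. On slide type 2, 753 of 4075 were positive and 1299 negative, so list counts here and below stand against a higher share there. As a group the chaperones lay above the other genes of slide type 1 by camera with a preset correlation (adjusted p = 1.65e-05), but not with an estimated correlation (adjusted p = 0.843). The adjustment gave many lists this same value of 0.843, here and below, so it does not rank them. For the chaperones of slide type 1 the unadjusted p of camera with an estimated correlation was 0.174. On slide type 2 camera gave adjusted p = 0.458, with a median of −0.12 and a mean of 0.19, and the group passed there without treatment 1 (adjusted p = 5.16e-05, median −0.064) or without treatment 3 (adjusted p = 0.000939, median −0.11), and without centring (adjusted p = 0.00266, median −0.036). With centring on probes with 1 symbol the median was −0.044. Without treatment 2 its direction there turned negative (adjusted p = 0.97, median −0.15). Hspa1a and Hspa1b, the inducible Hsp70 genes, were not analysed here.

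Immediate early and stress-activated genes gave 5 positive and 1 negative change among 13 members on slide type 1 (6 and 1 adjusted over the list alone), and 4 positive and 2 negative among 8 on slide type 2 (4 and 2 adjusted over the list alone). Beside Jun and Egr1, Fos had 0.47 ± 0.26 and Atf3, a stress-responsive transcription factor, 0.43 ± 0.36. By channel order, Fos had 0.09 with heat-shocked RNA in channel 1 and 0.86 with it in channel 2. Atf3 lost its call without treatment 1, and had 0.22 without treatment 3, whose value was 0.85 against 0.23 and 0.22. The growth regulator Myc lay on the negative side on both slide types, at −0.36 ± 0.14 and −0.49 ± 0.03, as did Zfp36l1, which binds AU-rich mRNA, at −0.40 ± 0.00. The list passed camera on slide type 1 (adjusted p = 0.00359; adjusted p = 0.843 with an estimated correlation). It did not pass on slide type 2 (adjusted p = 0.458), except without treatment 3 (adjusted p = 0.0263) and without centring (adjusted p = 0.0155). Without centring, Myc lost its call on both slide types and so did Zfp36l1. Hmox1, heme oxygenase 1, had 0.24 ± 0.11, a call that ended without treatment 1 or without treatment 3.

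Endoplasmic reticulum chaperones and stress genes lay on the negative side where they passed the test. On slide type 1, 5 of 12 members were changed, all 5 negative, and on slide type 2, 10 of 12, all 10 negative, with the same counts adjusted over the list alone. Hspa5 averaged 3 probes that ranged from −1.17 to −0.34. Calr, a calcium-binding chaperone, had −0.64 ± 0.17, Xbp1, a transcription factor of the unfolded protein response, −0.64 ± 0.34, and the disulfide isomerase Pdia6 −0.54 ± 0.14. The 2 probes of Pdia6 had −0.09 and −0.22 with heat-shocked RNA in channel 1, and −1.01 and −0.85 with it in channel 2. Camera gave adjusted p = 0.0136 on each slide type, and adjusted p = 0.843 with an estimated correlation. Calr lost its call when arrays were not centred, which also turned the median of slide type 1 from −0.15 to 0.15.

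Genes of cholesterol synthesis were changed on the negative side in 5 of 8 members measured on slide type 1 (6 adjusted over the list alone), and the 1 member on slide type 2, Msmo1, on the positive side. Msmo1, named after its value was seen, had 0.31 ± 0.05 over 2 probes that disagreed (−0.86 and 1.48), and lost its call without centring. Hmgcs1, which makes HMG-CoA, had −0.73 ± 0.12, the isomerase Idi1 −0.60 ± 0.01, the epoxidase Sqle −0.55 ± 0.04 and the squalene synthase Fdft1 −0.39 ± 0.04. Camera gave adjusted p = 0.000264, and adjusted p = 0.843 with an estimated correlation. None of the calls of Hmgcs1, Idi1, Sqle and Fdft1 held without centring, where the median on slide type 1 was −0.043 instead of −0.35. The glucose transporter Slc2a1 lay on the same side at −0.81 ± 0.17, whereas the glycolysis and hypoxia list to which it belongs gave 4 positive changes among 16 genes and no other negative change on slide type 1, and 1 positive among 5 on slide type 2. Aldoa, a glycolytic aldolase, had 0.35 ± 0.20 and adrenomedullin, Adm, 0.23 ± 0.07; Adm lost its call when any 1 treatment was left out, and Aldoa without treatment 1. That list passed camera on slide type 1 (adjusted p = 0.0208; adjusted p = 0.843 with an estimated correlation), but not without treatment 2 (adjusted p = 0.0906), without treatment 3 (adjusted p = 0.472) or without centring (adjusted p = 0.315).

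DNA replication genes were negative in all 7 changes among 19 members on slide type 1 (8 adjusted over the list alone), and gave 9 negative and 1 positive change among 15 on slide type 2. Rrm2, a subunit of ribonucleotide reductase, had −0.48 ± 0.06 over 3 probes that ranged from −0.86 to 0.29. The sliding clamp Pcna had −0.44 ± 0.00, the primase Prim1 −0.49 ± 0.17 and the licensing inhibitor Gmnn −0.32 ± 0.09. The list passed camera on slide type 1 (adjusted p = 0.00216; adjusted p = 0.843 with an estimated correlation) and not on slide type 2 (adjusted p = 0.0938). None of these 4 gene calls held without centring, which turned the median of slide type 1 from −0.12 to 0.18. Mitosis genes gave 1 positive and 4 negative changes among 24 on slide type 1 and 2 and 9 among 15 on slide type 2, with no call by camera (5 and 11 negative adjusted over the list alone). Cdc25c, a phosphatase that activates Cdk1, had 0.83 ± 0.17, and cyclin A2, Ccna2, −0.32 ± 0.05 on slide type 2.

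Splicing factors and hnRNPs were changed on the negative side in 27 of 39 members on slide type 2 and on the positive side in 2, but on slide type 1 in 4 negative and 0 positive of 37. Adjusted over the list alone, these counts were 27 and 2, and 5 and 1. Srsf3 had −0.80 ± 0.19 on slide type 1, and on slide type 2 Srsf2 had −0.61 ± 0.18 and Srsf1 −0.51 ± 0.03. Hnrnpa2b1 differed between slide types, with −1.15 ± 0.09 from the probe on slide type 2 and −0.02 ± 0.13 from that on slide type 1 (0.29 without centring). Camera gave adjusted p = 0.000264 on slide type 2, and adjusted p = 0.843 with an estimated correlation. Over all genes, 217 of 3838 were changed on the negative side on slide type 1 and 1299 of 4075 on slide type 2. The counts of the list on the 2 slide types therefore stand against unlike shares, and the difference between them was not tested.

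A further 4 lists passed camera on slide type 2 and not on slide type 1, a difference that was not tested. Their counts too stand against unlike shares of negative changes over all genes (1299 of 4075 on slide type 2, 217 of 3838 on slide type 1). On slide type 2, 10 of 14 proteasome genes were changed, all 10 negative, among them Psma5 (−0.40 ± 0.09), Psmc1 (−0.40 ± 0.10) and Psma2 (−0.39 ± 0.08). These values came mainly from the arrays with heat-shocked RNA in channel 2. Psma5 had −0.04 with it in channel 1 and −0.77 in channel 2, Psma2 −0.08 and −0.71, and the 2 probes of Psmc1 −0.08 and −0.81, and −0.17 and −0.54. Oxidative phosphorylation gave 23 negative and 2 positive changes among 39, with the cytochrome oxidase subunit Cox6b1 at −0.48 ± 0.06, the succinate dehydrogenase subunit Sdhd at −0.37 ± 0.06 on slide type 1, and Atp5g1 at 0.59 ± 0.03 from 2 probes that disagreed (−0.39 and 1.57). Translation factors gave 17 negative and 1 positive among 33, with the helicase Eif4a2 at −0.60 ± 0.03 and the cap-binding protein Eif4e at −0.61 ± 0.06, which had −0.35 ± 0.10 on slide type 1. The positive change was Eef2k, a kinase of an elongation factor and not itself a translation factor. Oxidative stress and metal response genes gave 12 negative and 1 positive among 16, with the glutathione transferases Gsta4 at −0.48 ± 0.04 and Gstm1 at −0.38 ± 0.14 and the transcription factor Nfe2l2 at −0.34 ± 0.10. The positive member was Txnip. Camera called these 4 lists on slide type 2 (adjusted p = 0.00351, 0.00602, 0.0291 and 0.0208), and with an estimated correlation adjusted p was 0.843, 0.843, 0.846 and 0.843. Adjusted over the list alone, these lists gave 11, 27, 20 and 13 negative and 0, 2, 2 and 1 positive changes. On slide type 1 the 4 lists gave 1, 2, 3 and 3 negative and 1, 3, 3 and 1 positive changes among 20, 28, 32 and 14 genes. Those positive changes included Eef2k and the methyltransferase Eef2kmt among translation factors, and the assembly factor Ndufaf6 in oxidative phosphorylation. The oxidative stress list there had a median of −0.13 (0.17 without centring) and adjusted p = 0.0684, and it passed without treatment 3 (adjusted p = 0.0403). Without centring, only the proteasome list among these 4 kept its call (adjusted p = 0.0146), and none of the named proteasome and glutathione transferase genes did. Translation factors lost their call without treatment 2 (adjusted p = 0.148), and the oxidative stress list without treatment 1 (adjusted p = 0.574) or without treatment 3 (adjusted p = 0.396).

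Cytosolic ribosomal protein genes had small medians of opposite sign on the 2 slide types, a difference that was not tested. The median was 0.10 over 36 genes on slide type 1, with 0 positive and 2 negative changes, and −0.12 over 61 genes on slide type 2, with 1 positive and 13 negative changes (8 negative adjusted over the list alone). These medians moved to 0.0054 on slide type 1 without treatment 3 and to −0.058 on slide type 2 without treatment 2, and to 0.41 and −0.035 without centring. Rpl24 had −0.29 ± 0.13 on slide type 2. The positive change was Rpl7l1, a ribosomal protein L7-like gene, at 0.62 ± 0.31, which had −0.27 ± 0.08 on slide type 1 over 2 probes at −0.39 and −0.15, a call lost without treatment 1 and a side turned without centring (0.034). Camera called both (adjusted p = 0.000264 on the positive and 0.0485 on the negative side), and with an estimated correlation adjusted p was 0.843 and 0.954. The call on slide type 1 was lost without treatment 3 (adjusted p = 0.49), and that on slide type 2 without treatment 1 (adjusted p = 0.239), without treatment 2 (adjusted p = 0.531), without centring (adjusted p = 0.273), with centring on probes with 1 symbol (adjusted p = 0.0986), with the first probe of each gene (adjusted p = 0.0526) or without large-ratio probes outside the stress lists (adjusted p = 0.0521).

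**Figure D2:**
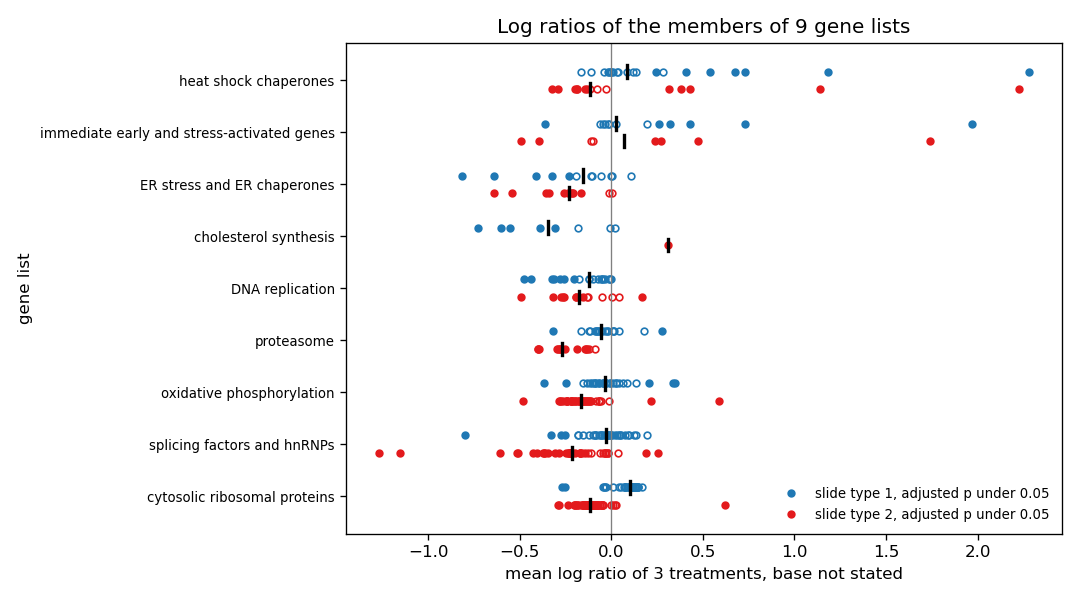
Mean log ratio over 3 treatments (horizontal axis, base not stated) of each member of 9 gene lists, slide type 1 in blue above slide type 2 in red. Filled points passed the test, open points did not, and black bars are list medians. Ribosomal protein genes have a median of 0.10 on slide type 1 and −0.12 on slide type 2.

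Genes of cell death and p53 response showed no common side. Fas, a death receptor, was negative on both slide types, at −0.78 ± 0.09 and −1.01 ± 0.10. Apoptosis genes gave 0 changes among 9 on slide type 1 and 4 positive and 2 negative among 14 on slide type 2, where Pdcd4 had 0.29 ± 0.05 over 2 probes at 0.18 and 0.40, a side that turned with heat-shocked RNA in channel 2 alone (−0.12). Listed p53 targets gave 0 positive and 1 negative change among 7 on slide type 1 and 2 of each among 7 on slide type 2; Cdkn1a was not analysed here. The list of chaperonin TRiC genes, which also holds prefoldin genes, gave 0 changes among 9 on slide type 1 and 1 positive and 4 negative among 6 on slide type 2. The TRiC subunit Cct4 had 0.26 ± 0.04 there (0.0059 ± 0.01 on slide type 1) and the prefoldin subunit Pfdn5 −0.32 ± 0.09. Camera called none of these lists. Histone genes gave 1 negative change among 5 on slide type 1, H3f3b at −0.43 ± 0.22, and 1 positive in the 1 gene on slide type 2. Developmental signalling targets gave 1 change on each side among 5 and 2 on each side among 9, with Id1, a target of BMP signalling, at 0.70 ± 0.20. The median and the camera direction differed in sign for the chaperones on slide type 2, p53 and developmental targets on both slide types, and translation factors, oxidative phosphorylation and yolk sac genes on slide type 1, in lists that did not pass there.

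The marker lists of embryonic cell types were short here, with 1 to 11 measured members. Erythroid genes gave 0 changes among 3 on slide type 1 and among 5 on slide type 2, where the embryonic globin Hbb-y had −0.14 ± 0.01 (limma adjusted p = 0.0543), passing only without treatment 2 among the 3 omissions. Yolk sac endoderm genes gave 1 positive change among 11 on slide type 1, Spp2 at 0.24 ± 0.03, and 2 negative among 3 on slide type 2. Trophoblast genes gave 0 changes among 6 and 1 negative in the 1 gene on slide type 2. Neural markers gave 1 negative change among 3, Tubb3 at −0.21 ± 0.04, and 1 negative in the 1 gene of slide type 2, Sox11 at −0.45 ± 0.07. Endothelial markers gave 1 negative change among 3, Esam at −0.27 ± 0.15. Tubb3 and Esam turned positive, short of the threshold, without centring, and Tubb3, Esam and Spp2 lost their calls without treatment 1, as did H3f3b and, on slide type 1, Eif4e. Tubb3, Esam and Spp2 also lost them without treatment 2, and Esam without treatment 3. Mesenchyme and neural crest markers gave 0 changes among 3 on slide type 1 and 4 negative among 6 on slide type 2, where the median was −0.29, with the collagen gene Col1a1 at −0.60 ± 0.29. Adjusted over the list alone, 2 of the 3 neural and 5 of the 6 mesenchyme genes were negative. Camera called none of the marker lists that it tested, but the mesenchyme list passed on slide type 2 without treatment 3 (adjusted p = 0.0403, median −0.36) and had adjusted p = 0.324 and a median of −0.17 without treatment 2, and no heart muscle marker was analysed here.

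Across all probes, 1235 of 7680 were changed on slide type 1, with 844 positive and 391 negative, and 4096 of 7680 on slide type 2, with 2219 positive and 1877 negative, at a limma adjusted p of 0.05. By gene, 437 of 3838 were changed on slide type 1 (220 positive, 217 negative) and 2052 of 4075 on slide type 2 (753 positive, 1299 negative). Most of these differences were small. Changed probes with a mean beyond 0.58 units, which is 1.5-fold if the base is 2 and 1.79-fold if the log is natural, numbered 269 on slide type 1 (242 positive, 27 negative) and 259 on slide type 2 (185 positive, 74 negative). Tested against that limit, 118 probes passed on slide type 1 (114 positive, 4 negative) and 120 on slide type 2 (104 positive, 16 negative). The named genes with the largest negative values also included Skp1 (−0.96 ± 0.15), a ubiquitin ligase subunit, Hmgn2 (−0.68 ± 0.17) and the importin Kpna2 (−0.66 ± 0.13) on slide type 1. Those of slide type 2 included Mpdu1 (−1.16 ± 0.14), Amd2 (−1.11 ± 0.12), Marcks (−0.95 ± 0.12, probes at −1.07 and −0.83), the histone chaperone Nasp (−0.83 ± 0.13) and the transcription factor Tgif1 (−0.83 ± 0.02). The largest positive values on single probes included Tgoln1 (1.42 ± 0.17), Scfd1 (1.26 ± 0.16), Rad52 (1.20 ± 0.10), Kdm2a (1.19 ± 0.10), Il4ra (1.18 ± 0.14), B4galt7 (1.18 ± 0.12) and Adnp (1.16 ± 0.11) on slide type 1. Those of slide type 2 included, beside Mst1r, Cacna1d (1.67 ± 0.07), Pafah1b1 (1.64 ± 0.08), Elovl3 (1.48 ± 0.03), Hps4 (1.39 ± 0.03), Zfp12 (1.37 ± 0.07) and P3h3 (1.33 ± 0.04). Some of these genes had other values on the other slide type, given here after they were seen and not tested for the difference. There Nasp had 0.15 ± 0.09 over 2 probes at −0.57 and 0.87, Marcks −0.19 ± 0.51, Mpdu1 −0.05 ± 0.14, Cacna1d 0.02 ± 0.08, Pafah1b1 0.06 ± 0.02 over 2 probes at −0.10 and 0.22, and Tgoln1 0.32 ± 0.10. Marcks passed there without treatment 1, at −0.47. Adnp had −0.14 ± 0.05 there, a call lost when any 1 treatment was left out and a side turned with heat-shocked RNA in channel 1 alone (0.33). Among named genes with such a probe outside the chaperone and immediate early lists, 13 had another probe, and 1 of these 19 other probes lay above 0.5. Other probes that were themselves changed above 1 unit were left out of the 19.

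The balance of sides depended on where 0 was set. Each array was centred on its median, and before centring the median over probes lay at 0.29 on slide type 1 and 0.11 on slide type 2. For treatments 1, 2 and 3 it was 0.25, 0.066 and 0.57, and 0.091, −0.11 and 0.35. Leaving these offsets in also widens the spread between treatments, so calls lost without centring cannot be put down to the place of 0 alone. Without centring, 1224 probes were changed on slide type 1, with 1210 positive and 14 negative, and 557 on slide type 2, with 422 positive and 135 negative. By gene the uncentred split was 263 positive and 5 negative on slide type 1, and 76 positive and 65 negative on slide type 2. With each array centred on the probes that carry 1 symbol, the gene split was 254 positive and 119 negative on slide type 1, and 1249 positive and 861 negative on slide type 2. Small differences on either side are therefore differences relative to the array median. Genes named above that also lost their calls without centring were Kpna2, Hmgn2, Eif4e, H3f3b and Sdhd on slide type 1, and Srsf1, Nfe2l2, Rpl24, Cox6b1, Sox11, Cct4, Pfdn5, Ccna2, Pdcd4, Adnp and Tgoln1 on slide type 2. The channel orders also differed, since 1202 of the 1235 changed probes of slide type 1 had the same side in both orders, but 2471 of 4096 on slide type 2. Arrays of 1 channel order alone gave 226 changed probes on slide type 2 with heat-shocked RNA in channel 1, and 700 with it in channel 2. Without treatment 1, changed genes numbered 178 on slide type 1 and 1227 on slide type 2, and changed probes 2315 on slide type 2.

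For 943 genes measured on both slide types, mean log ratios correlated at r = 0.28 across genes, which are not independent replicates. Of the 81 genes changed on both, 62 had the same side, 48 of them negative and 14 positive. Hsp90aa1, Fas, Myc and Eif4e were among them. The sides were unequal in number, with 53 of the 81 negative on slide type 1 and 1299 of all 2052 changed genes negative on slide type 2. Part of the agreement would therefore arise with unrelated sides, and it was not tested. Beyond the centring, this comparison sets levels across tables that were processed separately.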

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

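Of the tests in this part, those on channel bias and on shared sequence were chosen after the values they measure had been seen. Fisher's exact test on the share of unnamed probes, with its limit of 1 unit, was not planned either. Its p-values describe the pattern that prompted the test. Signals appeared in data that the gene comparisons leave out. A channel effect, measured with the sign of the arrays left as deposited and tested with limma over the 3 treatments, passed at 1705 probes of slide type 1 (741 positive, 964 negative) and at 1 probe of slide type 2. On slide type 2 the SD of this channel component over probes was 0.608 in treatment 2 against 0.225 and 0.282 in treatments 1 and 3.

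Probes with no gene symbol held many of the largest positive values. Of the 77 changed probes above 1 unit on slide type 1, 52 were unnamed, and of the 80 on slide type 2 also 52. Unnamed probes made up 67.5% and 65.0% of these sets, but 35.2% and 32.2% of all probes (Fisher's exact test over probes, two-sided, p = 9.57e-09 and 1.71e-09). Of the 104 unnamed probes, 99.0% lay above 0.5 in both channel orders, so nearly all were positive in each order. That share cannot weigh a channel bias, since the probes were picked for a mean above 1 over both orders. The channel component on slide type 1 had an SD of 0.15 to 0.25 in the 3 treatments, and the heat shock component 0.22 to 0.27. On slide type 2 these were 0.23 to 0.61 and 0.27 to 0.31. Such spreads do not decide on a channel bias either. At least 98.3% of the median of the unnamed probes stayed after a local trend was removed. That argues against a trend over the slide only if the probe numbers follow the slide layout, which was assumed and not checked. A feature smaller than the local window would not be seen. A candidate explanation is sequence shared by many clones, such as repeats or introns, but the values here cannot decide on it. For 13 named genes with such a probe outside the chaperone and immediate early lists, 5.26% of the 19 other probes lay above 0.5. Other probes themselves changed above 1 unit were left out, and the genes were picked for 1 extreme probe. Probes of a gene correlated only at r = 0.51 and 0.41 within slide types, so a low share was favoured in advance. Clones that carry another insert than annotated would give the same picture, no probe sequences were used here, and a response of repeat or unspliced RNA to heat was not tested directly.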

How the results depend on the processing

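Centring on probes with 1 symbol, removal of a position trend, the suffix as a fixed term, the use of arrays with or without the suffix and, for the lists, the omission of large-ratio probes were chosen after seeing the data. Main counts were 1235 and 4096 probes and 437 and 2052 genes on slide types 1 and 2. Without centring, genes numbered 268 on slide type 1 and 141 on slide type 2, and probes 557 on slide type 2. A common spread gave 1144 probes and 750 genes on slide type 2. On slide type 1, treating 6 swap pairs as independent gave 800 genes, and 12 arrays with a channel term gave 1956 probes and 918 genes. Arrays with the suffix B alone gave 797 probes and 216 genes there. Heat-shocked RNA in channel 1 alone gave 2402 probes and 839 genes on slide type 1, and 226 and 50 on slide type 2. In channel 2 alone it gave 776 and 194, and 700 and 24. The test against 0.58 units left 118 probes and 15 genes, and 120 and 31, because it asks for larger differences. Leaving out 1 treatment gave 881 to 1203 probes and 178 to 440 genes on slide type 1, and 2315 to 4920 probes and 1227 to 2209 genes on slide type 2. The lowest counts were those without treatment 1, except for probes on slide type 1, where it was that without treatment 2. The list count of 14 fell to 0 by camera with an estimated correlation (0 at an unadjusted p under 0.05 too, with a lowest unadjusted p of 0.069). It fell to 0 by fry (14 at an unadjusted p under 0.05), and was 10 to 15 in the other settings. The other causes were not tested.

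Of 113 called gene values, 107 kept side and call with a common spread, 108 with the position trend removed, 108 with centring on named probes, 112 with the robust prior, and 62 without centring. With heat-shocked RNA in channel 1 or channel 2 alone 61 and 54 did so, and against 0.58 units 31. Sides turned without centring for Hnrnpa2b1 (0.29), Tubb3 (0.094), Esam (0.035), Ywhaz (0.056), Hmga2 (0.10) Actg1 (0.054), Marcks (0.11), Mpdu1 (0.25) and Rpl7l1 (0.034) on slide type 1 and Hspa8 (0.057) on slide type 2. They turned with channel 1 alone for Hnrnpa2b1 (0.10), Marcks (0.26), Mpdu1 (0.016) and Cacna1d (−0.20) on slide type 1 and Hspa8 (0.10), Hbb-y (0.12), Adnp (0.33) and Vcp (0.20) on slide type 2, with channel 2 alone for Pdcd4 (−0.12), Pafah1b1 (−0.070) and Cct4 (−0.19), and with suffix B alone for Hnrnpa2b1 (0.0049), Mpdu1 (0.049) and Cct4 (−0.013). Cacna1d had −0.0086 with a common spread and Cct4 −0.022 with the position trend removed. With centring on named probes Hnrnpa2b1 had 0.024 and Hspa8 0.049. Leaving out 1 treatment, Hnrnpa2b1 ranged from −0.092 to 0.032, Marcks from −0.47 to 0.030, Mpdu1 from −0.098 to 0.027, Cacna1d from −0.026 to 0.056 and Cct4 from −0.0019 to 0.013 on slide type 1 and Hspa8 from −0.18 to 0.066 on slide type 2. No called value turned when a treatment was left out.

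With 3 treatments there are 4 sign patterns, so no share under 0.05 can be reached. The real pattern was the 1 of 4 with the most changes in each case, with 1235 and 4096 probes and 437 and 2052 genes, and the highest of the other patterns gave 0. No filter on dim or missing values was run, since intensities were not used and no value was missing. Each log ratio already pairs the 2 RNAs of an array, and fits of swap pairs with the treatment as a block were among the settings. The planned contrast and omissions by the number after the dot were not run, since these numbers are on different probes.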

Other observations

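All tests in this part were chosen after the values were seen, except the slope of treatment 2. Genes changed on the negative side on both slide types are given here, chosen after their values were seen. Of 53 genes negative on slide type 1 and changed on both, 48 were negative on slide type 2 as well, against 14 of 28 on the positive side. These shares stand against unlike backgrounds, since 1299 of the 2052 changed genes of slide type 2 were negative and 753 positive. Cyclin D2, Ccnd2, had −0.42 ± 0.06 and −0.52 ± 0.08 (SD, n = 3 treatments; 5 probes from −0.70 to −0.21 on slide type 2), nucleostemin, Gnl3, −0.39 ± 0.17 and −0.61 ± 0.17 (probes at −0.74 and −0.48), prohibitin, Phb, −0.49 ± 0.09 and −0.77 ± 0.09, and the O-GlcNAc transferase Ogt −0.47 ± 0.09 and −0.69 ± 0.04 (probes at −0.82 and −0.55). Fatty acid synthase, Fasn, had −0.38 ± 0.09 and −0.61 ± 0.13, the mRNA-binding protein Igf2bp1 −0.31 ± 0.04 and −0.52 ± 0.08, and the chromatin protein Hmga2 −0.20 ± 0.05 and −0.49 ± 0.11. Ywhaz had −0.25 ± 0.04 and −0.51 ± 0.08, and gamma-actin, Actg1, −0.25 ± 0.14 and −0.60 ± 0.21. None of these 9 calls on slide type 1 held without centring, where Ywhaz (0.056), Hmga2 (0.10) and Actg1 (0.054) turned positive, and those of Ccnd2, Ywhaz, Hmga2 and Igf2bp1 on slide type 2 did not hold either. Without treatment 1 the calls of Gnl3, Ywhaz, Hmga2, Igf2bp1 and Actg1 on slide type 1 were lost, and without treatment 2 those of Ywhaz, Hmga2 and Actg1. Dnaja1, an Hsp40 co-chaperone, lay on the positive side on both slide types, with 0.41 ± 0.22 (probes at 0.15 and 0.67) and 0.43 ± 0.37 (0.22 without treatment 2). Vcp, a protein-unfolding ATPase, had opposite sides, 0.97 ± 0.28 and −0.33 ± 0.09, the latter a call lost without centring and a side turned with heat-shocked RNA in channel 1 alone (0.20). Between 2 probes of a gene within a slide type, r was 0.51 over 717 genes and 0.41 over 685 genes.

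Treatment 2 differed from treatments 1 and 3 at stress genes and beyond them. Values of the chaperone list lay above the mean of the others in 28 of 36 cases, as for Hsp90aa1 (1.57 against 0.89 and 1.08, and 1.69 against 0.86 and 0.87 on slide type 2). Endoplasmic reticulum genes did so in 9 of 12 and 6 of 12 on slide types 1 and 2, and immediate early genes in 6 of 13 and 2 of 8. Ribosomal protein genes lay above in 5 of 36 and 0 of 61, oxidative phosphorylation genes in 13 of 28 and 2 of 39, and translation factors in 10 of 32 and 4 of 33. Egr1 (0.98 against 2.42 and 1.83) and Xbp1 (−0.25 against −0.83 and −0.84) lay nearer 0 in treatment 2. An artefact of single slides is argued against, since treatment 2 minus the others correlated between slide types at r = 0.740 over the 12 chaperone, immediate early and endoplasmic reticulum genes on both (one-sided permutation p = 0.0029 over genes, which are not independent, and r of 0.653 to 0.802 without any 1 gene). Over changed genes, the slope of treatment 2 on the mean of the other treatments was 1.09 on slide type 1 and 0.923 on slide type 2. These slopes cannot decide on 1 larger response at all genes. The genes were picked by a test over the same 3 treatments, and noise in the mean of the others lowers a slope. That r was chosen after a first test over 943 genes, where deviations correlated at 0.087, 0.245 and 0.241 for treatments 1, 2 and 3, and it is not particular to treatment 2, since treatments 1 and 3 gave 0.621 and 0.364 over the 12 genes. A brightness trend shared by both slide types stays open, since spot brightness was not available: the medians of treatment 2 minus the others were 0.18 and 0.19 for chaperones and −0.11 and −0.18 for ribosomal protein genes, a gap of at least 0.29, and a difference in heat dose or embryo stage may also be the source and was not tested.

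The side of the heat shock chaperones bears on the unstated direction. Of 18 values of the heat shock chaperone list past the threshold over both slide types, 12 were positive and 6 negative (66.7% positive). The 12 include the enzyme Hmox1. All 7 of the 18 values beyond 0.5 units were positive, a limit chosen after the values were seen. The 6 negative values were all on slide type 2, where 1299 of 4075 genes were negative and 753 positive. Heat shock proteins are textbook heat-induced genes, but these counts leave open whether the positive side is heat shock over control, and they set no sign.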
